A study of Mus musculus with 10 samples.

How the data were processed

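Gene expression was measured in the livers of 10 mice on 1-colour CodeLink oligonucleotide arrays, with 1 array per mouse. Per the labels' protocols, 5 mice were injected intraperitoneally with an antisense oligonucleotide (ASO) against the microRNA miR-122 at 50 mg/kg, 2 times a week for 4 weeks, and 5 control mice received saline on the same schedule. Livers were taken 2 days after the last dose, per the labels. The oligonucleotide carried 2′-O-methoxyethyl sugars on a phosphorothioate backbone, a chemistry that makes it stable in tissue. Male C57Bl/6 mice are named in the labels of the ASO group, and sex and strain are not stated in the labels of the saline group. Total RNA was isolated by caesium chloride centrifugation and silica columns with a DNase step and labelled with biotin, per the labels' protocols. The control was saline and not an oligonucleotide of another sequence, so effects of the oligonucleotide chemistry and effects of blocking miR-122 are part of the same difference.

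The deposited values are array intensities on a linear scale. Their medians lay between 1.03 and 1.05 on the 10 arrays, so the arrays were already on a common median, and 74 to 377 values per array were at or below 0, as background subtraction leaves them. The software, the background subtraction, the scaling and the reason for missing values are not given in the sources used here, and no detection flags were used. The brightest values of saline replicate 1 crowd below those of the other arrays, so its largest values were suspected of being clipped, and this was not tested. The number of arrays limits the precision.

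The table held 36227 probes. Of these, 115 were empty on all arrays, and 139 in all were left out because a group had fewer than 3 values, leaving 36088 probes. Values below the 10th percentile of all positive values (0.192) were set to it and log2 was taken (floor at -2.38), so differences of dim probes are understated. Probe annotation gave 1 gene symbol to 21615 probes, several genes to 681 and none to 13931. Symbols were looked up by Entrez ID in a gene table of assembly GRCm38.p6, where 21487 of the single-gene probes matched, 0 symbols changed and 128 kept the symbol of the annotation. Only single-gene probes were used to name genes, and 18012 genes had at least 1 tested probe.

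Differences are ASO minus saline on the log2 scale, fitted per probe with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates because no batch was given. Tests were two-sided with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A second count also required a fold of 1.5, the size named in the study's design text. Values are given as mean ± SD of log2 intensity with n = 5 mice per group, or as a log2 fold change with its standard error (SE). The design, the gene lists, the naming rule and the alternatives were fixed before the data were examined.

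Genes were named by a rule. In each direction up to 8 genes with the largest log2 fold change were taken among those past the threshold with a fold of at least 1.5, groups that did not overlap and a mean level above the median of all probes (0.03 on the log2 scale). From each gene list, up to 3 measured members with the smallest adjusted p were taken whether or not they passed. Clone names, Gm numbers and accessions were skipped. Other genes are named as chosen after their values were seen.

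The 37 gene lists covered reported miR-122 targets, lipid, sterol, bile acid and glucose metabolism, fetal liver genes, plasma proteins, immune responses, stress, drug metabolism, iron, sex-biased liver genes, the clock, ribosomal, mitochondrial and proteasome genes, and markers of liver cell types, blood and pancreas. Each gene was represented by its probe with the highest mean. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists, with camera at an estimated correlation and fry beside it. The adjustment over the list alone was computed for members as well. Each list's median was also set against 10000 random lists of genes with matching levels. A test of miR-122 seed matches in 3′ untranslated regions was planned and not run, because no transcript sequences were used here.

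Alternatives were quantile normalization, no floor, a pseudocount in place of the floor, only probes above the median level, eBayes with trend and robust, array weights and leaving out each array. For lists they also included the estimated correlation, the mean of all probes of a gene and fry. Cyclic loess normalization was added after the data were seen.

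The procedure was tested on simulated data for the ASO against saline comparison, drawn for 36088 probes from their real means and spreads with 200 probes changed. The changed probes were all taken from above the median level, so the recovery given here does not cover dimmer probes. It recovered 1 of 67 probes changed 1.5-fold (1.49%), 11 of 67 changed 2-fold (16.4%) and 55 of 66 changed 4-fold (83.3%), with 1 unchanged probe called. A list shifted in the simulation was called, and 0 of the others were. Its members were all raised by more than the median shift of most lists called in the real data. Its call therefore says little about smaller shifts. Simulated probes varied independently of each other, so the simulation does not test false calls of lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.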

Results

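The study asked what changes in liver messenger RNA when miR-122, the most abundant microRNA of hepatocytes, is blocked by an antisense oligonucleotide in living mice. Livers of 5 mice given the ASO were compared with livers of 5 mice given saline. Arrays within a group correlated at r = 0.949 to 0.982 across probes and arrays of different groups at 0.942 to 0.973. Each of the 5 ASO arrays had a lower median r with its own group (0.954 to 0.963) than with the saline group (0.955 to 0.969), and each saline array a higher one. The first principal component held 24.9% of the variance and separated the groups incompletely, since ASO replicate 5 (-27.0) lay among the saline arrays (-76.5 to -1.07). The brightest value on saline replicate 1 was 542, against 1198 to 2333 on the other arrays. On that array the abundant transcripts Alb, Apoa1, Serpina1e and Fth1 lay together between 8.86 and 8.89 on the log2 scale, against 9.18 to 10.35 on the other saline arrays.

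Few single transcripts separated the groups strongly, and the largest increase among genes taken by the naming rule was in an imprinted noncoding RNA. Rian, a maternally expressed long noncoding RNA, rose from 0.13 ± 0.68 to 2.60 ± 0.44 (SD, n = 5 per group), a log2 fold change of 2.47 ± 0.33 (SE, limma adjusted p = 0.0448). Slc1a4, a neutral amino acid transporter, rose by 1.37 ± 0.20 (adjusted p = 0.0448), and Slc38a9, an amino acid sensor of the lysosome, by 1.19 ± 0.18 (adjusted p = 0.0456). Increases also passed in the photoreceptor phosphodiesterase gene Pde6c (1.44 ± 0.22) and in the xylosyltransferase gene Xxylt1 (1.31 ± 0.19). A second probe of Slc38a9 gave 0.27 ± 0.29 and was not called, and the other Rian probes gave 1.54 ± 0.34 and 0.39 ± 0.29 and were not called either. Outside the rule, the clone 4930579F01Rik, chosen after its values were seen, had the smallest adjusted p of all probes (0.00792) with a log2 fold change of 2.99 ± 0.28.

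Among genes taken by the naming rule, the largest decrease was in Gas1, a membrane protein of growth-arrested cells, which stood at 3.26 ± 0.42 in saline mice (SD, n = 5 per group) and had a log2 fold change of -2.22 ± 0.31 (SE, limma adjusted p = 0.0448). Tab2, an adaptor in signalling to NF-kB, fell by 2.01 on the log2 scale, and Omd, a matrix proteoglycan, by 1.85. The chemokine gene Ccl9 fell by 1.63 (SE 0.19, adjusted p = 0.0204) and Ddah1, which breaks down methylated arginines, fell by 1.55 (SE 0.18, adjusted p = 0.0204). Myoz3 had a log2 fold change of -1.42 ± 0.20 at the called probe and 0.24 ± 0.21 at another probe. Defb1, a beta-defensin gene whose mean level lay below the median and which was chosen after its values were seen, had a log2 fold change of -2.77 ± 0.30 (adjusted p = 0.0198).

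In all, 23 of 36088 probes passed the adjusted threshold, 11 higher and 12 lower in the ASO group, with folds of 2.11 to 8.01, so the count at 1.5-fold was also 23. In each of the 23 the groups did not overlap, and 6 of the probes had no single gene. At an unadjusted p under 0.05 there were 4057 probes (11.2%), 1654 higher and 2403 lower. The excess of lower probes was nearly absent under quantile normalization (1874 higher and 1922 lower) and larger with only probes above the median level (637 higher and 1950 lower). Groups did not overlap in 854 probes (2.37%, against 0.794% by chance). The count of 23 went to 1 without saline replicate 1, 0 without saline replicate 2, 3, 2 and 2 without saline replicates 3, 4 and 5, and 16, 10, 0, 1 and 1 without ASO replicates 1 to 5. With values at or below 0 set missing in place of the floor it was 7, and with only probes above the median level it was 73.

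**Figure D1:**
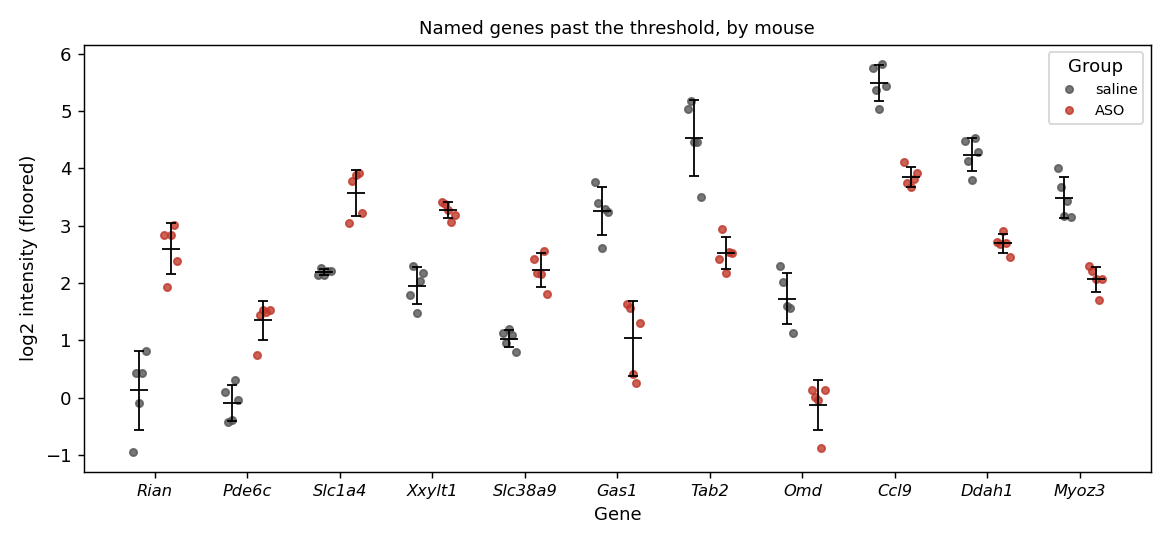
Log2 intensity (vertical axis) of the 11 named genes past the threshold (horizontal axis). Points are mice (saline grey, ASO red, n = 5 each), dashes are group means and bars are SD. In each gene the ASO mice lie on 1 side of the saline mice.

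Reported miR-122 targets were higher as a group after the ASO. Of 19 measured genes, 16 were higher and 3 lower, with a median log2 fold change of 0.27 (camera adjusted p = 0.000255, and adjusted p = 0.136 with an estimated correlation). Bckdk, the kinase that shuts off branched-chain amino acid breakdown, went from 2.33 ± 0.34 to 3.55 ± 0.47 (SD, n = 5 per group), a log2 fold change of 1.22 ± 0.25. Ndrg3 was higher by 0.92 ± 0.22 and Cd320, the transcobalamin receptor, by 0.69 ± 0.20. Adjusted over the list alone 3 genes passed (Bckdk 0.00852, Ndrg3 0.0123, Cd320 0.0315), and over all probes 0 did. Some of these targets were reported from miR-122 inhibition in mouse liver, possibly in these same animals, so the list is not independent evidence of its direction.

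Genes of the fetal liver program were also higher, 10 of 11 measured, with a median of 0.21 (camera adjusted p = 0.00372, and adjusted p = 0.183 with an estimated correlation). H19, an imprinted noncoding RNA, had a log2 fold change of 0.75 ± 0.25, Afp, which encodes alpha-fetoprotein, 0.58 ± 0.20, and Tspan8 0.57 ± 0.23. None of the 11 passed adjusted over the list alone in limma, where 4 had an unadjusted p under 0.05 and all 4 were higher. The median lay within the range of level-matched random lists (-0.27 to 0.22), and fry did not make the call (adjusted p = 0.0861). It was 0.36, 0.13, 0.45 and 0.34 without ASO replicates 1, 2, 4 and 5, 0.34 with no floor and 0.57 with only probes above the median level.

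Genes that build fatty acids and triglycerides were lower in the ASO group. Of 22 measured genes, 19 were lower, with a median log2 fold change of -0.77 (camera adjusted p = 2.35e-06, and adjusted p = 0.196 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, went from 3.44 ± 0.76 to 1.49 ± 0.76 (SD, n = 5 per group), a log2 fold change of -1.94 ± 0.42. Srebf1, a transcription factor that drives fatty acid synthesis, had -1.33 ± 0.28, and Scd1, the stearoyl-CoA desaturase, -1.10 ± 0.25. Adjusted over the list alone 8 genes passed, all lower, and over all probes 0 did.

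Cholesterol synthesis genes were lower as well, 14 of 17 measured, with a median of -0.43 (camera adjusted p = 0.00318, and adjusted p = 0.456 with an estimated correlation). Pmvk, phosphomevalonate kinase, had a log2 fold change of -1.37 ± 0.31, and Nsdhl -0.98 ± 0.22, and these 2 passed adjusted over the list alone (0.00834 each). Cyp51 had -0.75 ± 0.26 and did not pass. The call was lost without saline replicate 1 (adjusted p = 0.0572) and with fry (adjusted p = 0.183), and the median was -0.28 without ASO replicate 3. Genes for sterol uptake and its control were not called (8 measured, adjusted p = 0.705), with Insig1 at 0.34 ± 0.20, Abca1 at -0.32 ± 0.21 and Scap at -0.28 ± 0.21. Without saline replicate 1 these were 0.22, -0.20 and -0.16, and Scap was -0.15 under quantile normalization and -0.18 under cyclic loess.

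Fatty acid oxidation genes were lower with a smaller shift, 16 of 21 measured, median -0.22 (camera adjusted p = 0.0371, and adjusted p = 0.305 with an estimated correlation). Slc25a20, the carnitine carrier, had a log2 fold change of -1.46 ± 0.31, Etfdh -1.94 ± 0.50 and Acaa2 -0.89 ± 0.25, and these 3 passed adjusted over the list alone. The median lay within the range of level-matched random lists (-0.31 to 0.07, 11.4th percentile) and was -0.14 without saline replicate 1 and -0.41 without ASO replicate 5. This call was lost without saline replicate 1 (0.159), saline replicate 3 (0.0636), ASO replicate 1 (0.0529) or ASO replicate 4 (0.114). Lipid droplet genes were not called (adjusted p = 0.971), with Plin4 at 0.94 ± 0.42, Cideb at -0.38 ± 0.18 and Plin2 at -0.67 ± 0.37. Plin4 was 0.53 without saline replicate 4, Cideb -0.23 under quantile normalization and Plin2 -0.32 without ASO replicate 3. Apolipoprotein genes were not called either (adjusted p = 0.741), with Scarb1 at -0.66 ± 0.29, Apoc4 at -0.53 ± 0.25 and Apoa1 at 0.50 ± 0.26 (0.27 without saline replicate 1 and 0.23 under quantile normalization). Bile acid genes had a median of -0.37, and -0.23 under quantile normalization (camera adjusted p = 0.126, fry adjusted p = 0.0269), with Baat at -0.81 ± 0.24, Nr0b2 at -1.43 ± 0.46 and Cyp8b1 at -1.17 ± 0.43.

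Liver glucose and glycogen genes were lower, 12 of 14 measured, with a median of -0.56 (camera adjusted p = 0.00227, and adjusted p = 0.105 with an estimated correlation). Igfbp1, a binding protein of insulin-like growth factors, went from 2.18 ± 0.38 to 0.99 ± 0.32 (SD, n = 5 per group), and Pfkl, the liver phosphofructokinase, from 2.58 ± 0.29 to 1.66 ± 0.51. These 2 genes passed adjusted over the list alone (0.00296 and 0.0267). Pygl, glycogen phosphorylase, had a log2 fold change of -1.02 ± 0.36 and did not pass. Other glycolysis genes, some of them bright in these livers such as Ldha (mean log2 level 8.54), were not called (adjusted p = 0.705). Pkm was at 0.62 ± 0.24 (0.41 without ASO replicate 4), Ldha at 0.40 ± 0.16 and Tpi1 at -0.43 ± 0.17.

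**Figure D2:**
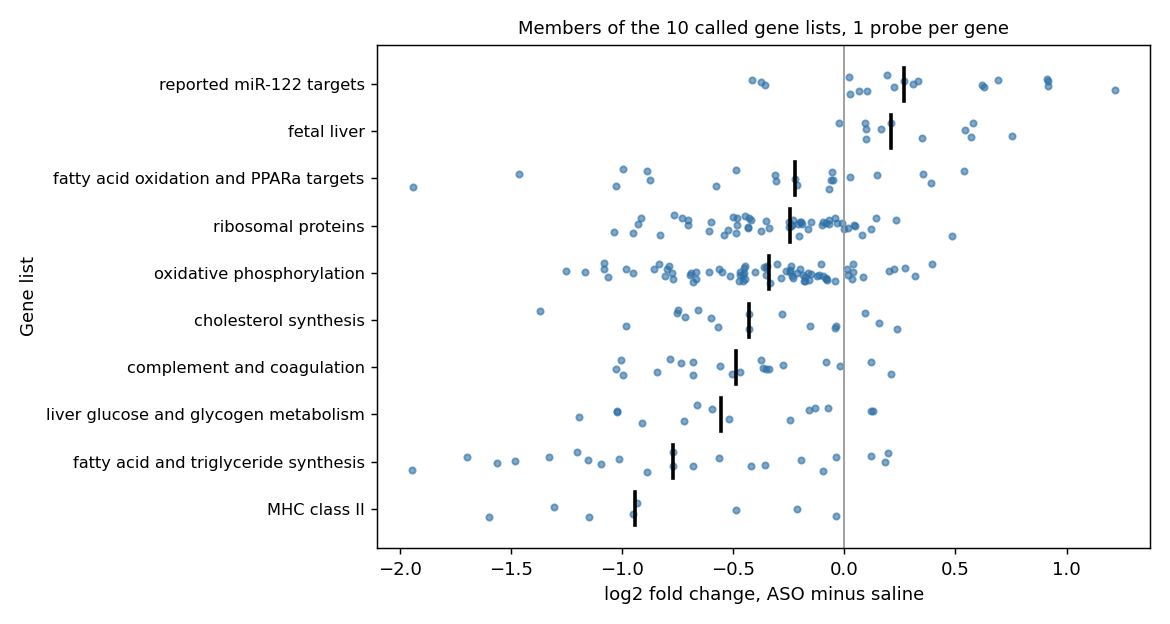
Log2 fold change, ASO minus saline (horizontal axis), of the measured members of the 10 called gene lists (vertical axis), with 1 probe per gene. Each point is a gene and each black bar the median of its list. The medians run from -0.94 in MHC class II to 0.27 in reported miR-122 targets.

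Complement and coagulation factors, which hepatocytes secrete into plasma, were lower in the ASO group. Of 20 measured genes 18 were lower, with a median of -0.49 (camera adjusted p = 0.000112, and adjusted p = 0.0969 with an estimated correlation). C9 had a log2 fold change of -1.03 ± 0.24, Hc, which encodes complement component C5, -0.68 ± 0.19, and F9, coagulation factor IX, -0.79 ± 0.22. With Pros1, these were the 4 genes that passed adjusted over the list alone. Acute phase genes were not called (adjusted p = 0.196, 0.0160 and lower without ASO replicate 5, 0.822 without ASO replicate 3), with Cp at -0.75 ± 0.25, Fga at -0.64 ± 0.24 and Orm1 at -0.85 ± 0.33. Hepatocyte markers were not called (adjusted p = 0.334), with Alb at 0.57 ± 0.27 (0.33 without saline replicate 1 and 0.28 under quantile normalization), Glul at 0.48 ± 0.23 and Arg1 at -0.32 ± 0.16. Iron genes were not called (adjusted p = 0.629), with Tfr2 at -0.93 ± 0.28, Ftl1 at -0.66 ± 0.21 and Fth1 at -0.61 ± 0.31. Because Fth1 was among the transcripts crowded together on saline replicate 1, its size is uncertain (-0.74 without that array).

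Genes of MHC class II, which present antigen on macrophages, dendritic cells and B cells, were lower in the ASO group. All 8 measured genes of the list were lower, with a median of -0.94 (camera adjusted p = 0.000142, and adjusted p = 0.136 with an estimated correlation). The list also held Ciita and Cd86, which are not MHC class II molecules themselves. H2-Aa went from 3.67 ± 0.35 to 2.52 ± 0.40 (SD, n = 5 per group), Cd74, the invariant chain, from 5.41 ± 0.41 to 4.46 ± 0.27, and H2-DMa from 1.41 ± 0.35 to 0.48 ± 0.51. Adjusted over the list alone 5 genes passed. Kupffer cell and macrophage markers had a median of -0.26 with 17 of 20 lower and were not called (adjusted p = 0.207), with Mpeg1 at -1.45 ± 0.48, Fcer1g at -0.74 ± 0.44 and C1qa at -0.67 ± 0.41. Their median was 0.01, with the direction turned, without ASO replicate 2, and -0.40 without ASO replicate 4, where the list was called lower (adjusted p = 0.0127). Fcer1g was -0.32 and C1qa -0.33 without ASO replicate 2. Lymphocyte markers had a median of -0.25 (-0.14 without saline replicate 1, -0.15 and -0.07 without ASO replicates 2 and 3) and were not called (camera adjusted p = 0.327, fry adjusted p = 0.0170), with the B cell gene Ms4a1 at -0.57 ± 0.16, Klrb1c at -0.91 ± 0.36 (-0.60 without saline replicate 4 and -1.76 with no floor) and Cd79a at -0.51 ± 0.23.

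Interferon response genes were not called as a list (camera adjusted p = 0.118), and 4 of 22 members were lower adjusted over the list alone. These were Rsad2 (-1.31 ± 0.29), Cxcl9 (-1.07 ± 0.29), Irf7 (-0.98 ± 0.29) and Cxcl10 (-1.68 ± 0.52). Neutrophil genes were not called (adjusted p = 0.187), with Elane at 0.74 ± 0.19, the 1 gene that passed adjusted over the list alone, Ltf at 0.80 ± 0.32 and Cxcr2 at 0.33 ± 0.19.

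**Figure D3:**
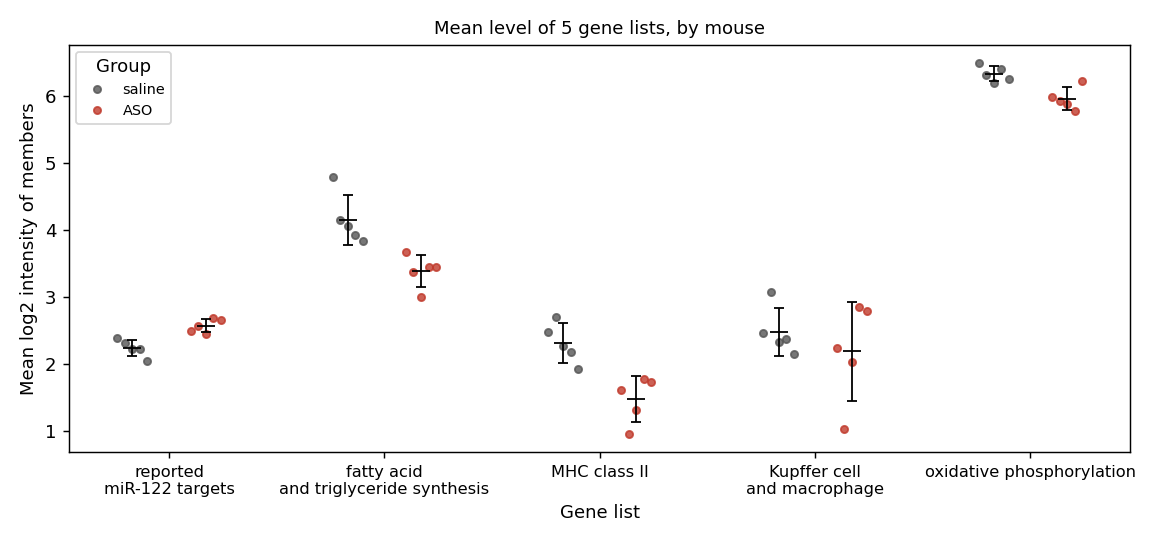
Mean log2 intensity of the measured members (vertical axis) of 5 gene lists (horizontal axis) by mouse. Points are mice (saline grey, ASO red, n = 5 each), dashes are group means and bars are SD. Groups overlap for Kupffer cell and macrophage markers, whose ASO mice spread more widely than the saline mice. They also overlap for oxidative phosphorylation, where ASO replicate 5 (6.23) lies above saline replicate 3 (6.20).

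Mitochondrial oxidative phosphorylation genes and ribosomal protein genes, both highly expressed, were slightly lower in the ASO group. Of 74 oxidative phosphorylation genes, 63 were lower, with a median of -0.34 (camera adjusted p = 6.90e-07, and adjusted p = 0.174 with an estimated correlation). Cox7a1, which was dim for this list (mean log2 level 0.21), had a log2 fold change of -1.06 ± 0.19. Cox6a1 had -0.95 ± 0.18 and Uqcrfs1 -0.79 ± 0.18, and 8 genes of the list passed adjusted over the list alone. Of 54 ribosomal protein genes, 46 were lower, with a median of -0.24 (camera adjusted p = 0.000807, and adjusted p = 0.136 with an estimated correlation). Camera used the 53 of them without a missing value. Rpl10a had -0.91 ± 0.23, Rps27l -0.76 ± 0.21 (4 saline mice, missing on saline replicate 1) and Rpl8 -0.95 ± 0.29. None of the list passed adjusted over the list alone in limma, where 10 had an unadjusted p under 0.05. Probes above the median level had a median log2 fold change of -0.08 as deposited and 0.02 after quantile normalization, and both lists stayed lower under it. The ribosomal median was -0.16 under cyclic loess, an alternative added after the data were seen.

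By camera, which tests a shift in 1 direction, the clock gene list was not called (7 higher and 7 lower, adjusted p = 0.730). Members that move in opposite directions cancel in that test. In the form of fry that disregards direction, the list had an adjusted p of 0.00846. That form also passed other lists that camera did not call, such as interferon response (0.00596). At an unadjusted p under 0.05 in limma, 2 clock genes were higher and 3 lower. Arntl, the partner of Clock in the core clock, went from 3.57 ± 0.36 to 2.50 ± 0.37 (SD, n = 5 per group) and passed adjusted over the list alone (0.00876). Nr1d1 had -1.19 ± 0.38 and Clock -0.77 ± 0.27, and neither passed.

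Markers of other cells did not pass as lists. The adjusted p was 0.705 for stellate cell and matrix genes (Col5a1 -0.59 ± 0.20, Ccn2 0.50 ± 0.25, Col3a1 -0.34 ± 0.18, and -0.18 under quantile normalization and -0.22 under cyclic loess), 0.334 for endothelial genes (Cdh5 0.87 ± 0.28, Stab1 0.49 ± 0.32, Vwf 0.24 ± 0.21) and 0.971 for bile duct genes (Krt19 -0.62 ± 0.24, Cldn7 0.32 ± 0.19, Prom1 -0.52 ± 0.43). Without ASO replicate 2 the endothelial list was called higher (adjusted p = 0.0281). It was 0.865 for red blood cell genes (Alas2 -0.51 ± 0.29, Slc4a1 0.27 ± 0.19, Epb42 0.11 ± 0.19) and 0.971 for pancreas genes (Cel -0.84 ± 0.36, Cela3b 0.33 ± 0.21, Prss2 -0.38 ± 0.34). Single arrays or settings moved several of these values. Without ASO replicate 4 Stab1 was 0.30 and Vwf 0.10, without saline replicate 4 Stab1 was 0.29, and under quantile normalization Vwf was 0.38. Prom1 was -0.10 without ASO replicate 5 and -0.34 without saline replicate 4, Krt19 -0.40 without ASO replicate 3 and Cldn7 0.21 without saline replicate 1. Alas2 was -0.30 without ASO replicate 2, Slc4a1 0.15 without saline replicate 1, Cela3b 0.21 and Prss2 -0.06 without ASO replicate 3, Prss2 -0.59 with no floor or without ASO replicate 4, and Epb42 0.00 without saline replicate 3, 0.20 without saline replicate 4, and 0.21 and 0.05 without ASO replicates 1 and 5. Sex-biased genes were not called in either set, at 0.6 for male-biased genes (Cspg5 -1.01 ± 0.30, C6 -0.84 ± 0.42, Serpina1e 0.38 ± 0.27, and 0.13 without saline replicate 1 and 0.02 under quantile normalization) and 0.164 for female-biased genes (Acot3 0.81 ± 0.26, Cyp2b13 1.12 ± 0.40, Cyp17a1 1.11 ± 0.44).

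Stress and growth programs were not called either. The adjusted p was 0.334 for the cell cycle (12 higher and 10 lower, Mki67 0.76 ± 0.25, Ccna2 0.62 ± 0.24, Rrm2 -0.40 ± 0.19), 0.705 for drug metabolism under the receptors CAR and PXR (Abcc3 -0.82 ± 0.25, Cyp2b13 1.12 ± 0.40, Cyp2b10 2.05-fold lower) and 0.702 for targets of NRF2 (Txnrd1 -0.80 ± 0.24, Ephx1 -0.78 ± 0.31, Cbr3 0.27 ± 0.25). It was 0.705 for endoplasmic reticulum stress (Sdf2l1 -1.52 ± 0.63, Creld2 -0.90 ± 0.37, Atf3 0.40 ± 0.22), 0.277 for targets of p53 (Tnfrsf10b -0.60 ± 0.26, Btg2 -0.52 ± 0.29, Bbc3 -0.39 ± 0.25), 0.207 for the lysosome (Lamp2 -1.56 ± 0.45, Lamp1 -0.83 ± 0.25, Npc2 -0.76 ± 0.34) and 0.6 for the proteasome (Psmd7 -0.97 ± 0.38, Psmd2 -0.84 ± 0.38, Psmd6 -0.35 ± 0.17). Single arrays carried part of these values, since Sdf2l1 was -0.92 without ASO replicate 2, and Ephx1 was -0.51, Btg2 -0.26 and Psmd7 -0.64 without ASO replicate 3. Cbr3 was 0.12 without saline replicate 5 and also without ASO replicate 4.

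Of the 37 lists, 10 were called by camera, 2 higher and 8 lower. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.0969. By fry 9 lists passed, 7 of them among the 10. Against level-matched random lists, the medians of fetal liver and fatty acid oxidation lay within the 95% range and those of the other 8 called lists outside it. Lists not called also lay outside it, namely bile acid, interferon response, lymphocyte and p53 genes below and hepatocyte markers above. The range thus did not separate called lists from the rest. Random lists also leave out the correlation between members of a list. None of the 650 measured list members passed over all probes.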

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

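In each group of 5 arrays, the highest or lowest array was looked for whose gap to the next took most of the group's range, for the named genes, the list means and the measures of each array. Of 331 groups tested, 17 had such an array (5.14%), and chance gives about 1 in 20. The arrays involved were spread over both groups, with at most 3 on any 1 array. Values are log2 intensities unless stated, and no explanation was tested for them.

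Among genes past the threshold, Pde6c on ASO replicate 1 was at 0.74 with the others between 1.45 and 1.54, and Omd on ASO replicate 4 was at -0.88 with the others between -0.04 and 0.14. The miR-122 target Bckdk was at 2.72 on ASO replicate 3 (others 3.67 to 3.88). Acly was at 2.80 on ASO replicate 1 (others 0.97 to 1.46), the highest of the ASO mice and below all saline mice. Rpl10a was at 6.18 on ASO replicate 3 (others 7.10 to 7.38). In the saline group, Tpi1 was at 3.06 and H2-DMa at 0.79 on replicate 5, Fcer1g at 2.32 on replicate 2 and Ccna2 at -1.27 on replicate 1. Saline replicate 4 stood apart for Klrb1c (0.19), Cel (-0.32) and Ftl1 (8.42).

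Among list means, saline replicate 1 was highest for cholesterol synthesis (5.20, others 4.34 to 4.57) and for the clock (1.79, others 1.52 to 1.56). ASO replicate 4 was highest for the cell cycle (0.85, others 0.37 to 0.50) and ASO replicate 5 for the proteasome (5.73, others 5.31 to 5.42). The 99th percentile of intensity was 221 on saline replicate 3, against 194 to 201 on the other saline arrays.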

How the results depend on the processing

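Counts of called probes and list calls both moved with the processing. Cyclic loess normalization was chosen after seeing the data. From 11 higher and 12 lower probes, the counts went to 3 and 4 with no floor, 27 and 46 with only probes above the median level, and 17 and 22 under cyclic loess. Lower probes went to 22 with a pseudocount and 27 with trend and robust. Quantile normalization and array weights stayed within 1.5 times, and counts at 1.5-fold were the same as these. The filter tests fewer probes, and for the others the cause was not tested. Leaving out 1 array gave 0 to 5 higher and 0 to 11 lower probes, with fewer samples. All 23 called probes kept their direction under each alternative that measured them and had an unadjusted p under 0.05 there. They were picked from these same arrays with groups that did not overlap, so leaving out 1 array could not turn a direction.

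With an estimated correlation, camera called 0 lists higher and 0 lower. The adjusted p was then 0.136 for reported miR-122 targets, MHC class II and ribosomal proteins, 0.456 for cholesterol synthesis, 0.196 for fatty acid and triglyceride synthesis, 0.305 for fatty acid oxidation, 0.105 for glucose and glycogen, 0.183 for fetal liver, 0.0969 for complement and coagulation and 0.174 for oxidative phosphorylation. With fry 1 list was called higher, and cholesterol synthesis (0.183), fatty acid oxidation (0.0581) and fetal liver (0.0861) did not pass. Fatty acid oxidation also lost its call under quantile normalization (0.0528), no floor (0.0537), only probes above the median level (0.263), array weights (0.0521) and cyclic loess (0.0919). Leaving out 1 array gave adjusted p from 0.000461 to 0.0572 for cholesterol synthesis and from 0.0179 to 0.159 for fatty acid oxidation. The cause was not tested for these.

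The 11 named genes past the threshold kept their direction in each setting. The naming rule required groups that did not overlap, so leaving out 1 array could not turn it. The call was lost for 9 of the 11 genes with no floor, and for Tab2 and Xxylt1 with array weights. Leaving out 1 array at a time lost a call in 99 cases of a gene and an array. All were lost without saline replicate 2 or ASO replicate 3. Lists not called in the main setting became called in 5 cases. These were endothelial genes without ASO replicate 2 (higher, 0.0281), macrophage markers without ASO replicate 4 (lower, 0.0127), acute phase genes without ASO replicate 5 (lower, 0.0160), and with fry bile acid genes (lower, 0.0269) and lymphocyte markers (lower, 0.0170). Acly, Igfbp1 and Cox7a1 passed when only probes above the median level were tested. Values of several named genes that did not pass, and medians of lists not called, moved by over 1.5 times in some settings, while no gene of the naming rule that passed over all probes or over its list alone did. Seed matches of miR-122 in untranslated regions were not run in any setting. Replicate numbers only name arrays, and no paired analysis was possible because the labels pair no mice. Dim probes are limited by the floor, at which 9.22% to 12.7% of the values of an array lay.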

Other observations

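The tests of a single odd probe, of both parental sides of the imprinted region and of scaling for oxidative phosphorylation genes were chosen after the results were seen.

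Just short of the threshold lay further genes, chosen after their values were seen, with groups that did not overlap. Lad1, a basement membrane anchor protein, was higher at both of its probes (1.16 ± 0.18, limma adjusted p = 0.0523, and 1.36 ± 0.25, adjusted p = 0.110). Noct, a clock-regulated phosphatase also called nocturnin, had a log2 fold change of 2.13 ± 0.36 (adjusted p = 0.0803), and the peroxisomal membrane gene Pxmp4 had 1.30 ± 0.22 (adjusted p = 0.0801). On the lower side, the water channel gene Aqp8 had -1.59 ± 0.27 and the receptor kinase gene Grk5 -2.35 ± 0.40 (adjusted p = 0.0803 each). A second defensin gene, Defb19, had -1.33 ± 0.24 (adjusted p = 0.0958).

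Other splits of the same 10 arrays into 5 and 5 were compared with the real one, drawing 100 of the 126 possible splits. The real split gave 23 called probes, and the highest of the others gave 1, so 1 of 100 splits, the real one, gave as many. That is the smallest share that 100 splits can give, so chance is unlikely for that count but not excluded. The same held at 1.5-fold, with 1 of 100 and a highest other of 1. For gene lists called, 4 of 100 splits gave as many as the real 10, a share under the 5% set beforehand. The other splits among these each kept 4 saline arrays in 1 group, so they hold much of the real contrast. The highest other gave 12 and the median of the others was 2, so chance is not excluded for the number of lists. For the 4057 probes at an unadjusted p under 0.05, 5 of 100 splits gave as many and the highest other gave 5155, so chance cannot be excluded for that count.

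Rian and Meg3, noncoding RNAs of the same imprinted region, had their largest increases at 1 probe each (2.47 ± 0.33 and 2.70 ± 0.51, the latter with limma adjusted p = 0.110). For Rian, 1 of the 2 other probes was higher with groups that did not overlap, which argues against a single odd probe. For Meg3, 0 of the other 3 probes were, with values of -0.23, -0.22 and 0.53, so the Meg3 increase may belong to that probe or to the transcript form it reads. The paternally expressed genes Dlk1, Rtl1 and Dio3 had a median of 0.26, but 0 of the 3 lay above the median level, so a change of both parental sides cannot be told apart from a change of the maternal RNAs. The strain of the saline mice, which the labels do not state, was not tested as a source.

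The lower oxidative phosphorylation and ribosomal protein genes may reflect scaling between arrays, since probes above the median level had a median log2 fold change of -0.08. That shift was not largest at the level of these genes. It was -0.14 at log2 levels from 4 to 6 and -0.06 from 6 to 8, where both lists had their median level (6.86 and 7.12). Under quantile normalization, which removed the lower median of probes above the median level, the list medians were -0.25 and -0.19. The 95% intervals of the difference in list means ran from -0.48 to -0.15 and from -0.34 to -0.16. Without saline replicate 1, the array with the lowest maximum, the medians were -0.31 and -0.25 with intervals from -0.56 to -0.12 and from -0.43 to -0.14. These values argue against either as the whole cause. The ASO treatment, the oligonucleotide chemistry and RNA quality stay open and were not tested apart.

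Of the 14 clock genes only Arntl passed adjusted over the list alone, while Clock and Nr1d1 did not, nor did Ciart (0.55 ± 0.21), Tef (0.64 ± 0.26), Npas2 (0.38 ± 0.31) and Cry1 (-0.04 ± 0.24), which were picked after their values were seen. The lower Arntl may come from ASO mice being taken later in the day, a time the labels do not give. In a test set before the values of these genes were seen, 11 other clock-controlled genes that peak in the evening were taken. Of these 6 were higher and 5 lower, with a median of 0.03 at the 74.6th percentile of level-matched random lists and a difference in list means of -0.04 (95% interval -0.38 to 0.29). Bhlhe41, Rgs16, Wee1 and Coq10b among them were dim, with mean log2 levels of -2.2, -2.1, -1.6 and -1.5. The floor can understate differences of such genes, which limits the test. The hour of sampling and an effect of the ASO on the clock cannot be told apart from these values.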
